A study of Mus musculus with 36 samples.

How the data were processed

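The starting point was a table of raw values for 36 arrays of 45281 probes. Per the labels the arrays were scanned on an iScan, and the intensities were deposited as raw values, with no normalisation between arrays that the labels or the values show. Between 30.18% and 36.61% of the intensity values of an array lie below zero, from which it was inferred that background had been subtracted, and the software is not given in the sources used here. The second column of each array is a detection p-value per the file headers and was deposited beside its intensity, and its steps in the values are those of a rank among 936 negative controls per array. The authors deposited a second set of values on a log2 scale, which they state was made with the package lumi by variance stabilisation and robust spline normalisation, and the version of lumi is not stated. Ranks within each array were the same in both sets, so columns and samples match.

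Raw intensities were normalised with the neqc function of limma, which estimates background from the detection p-values, adds an offset of 16, takes log2 and quantile normalises. Probes with a detection p under 0.05 on at least 3 arrays were kept, 23999 in number. The probe with the highest mean stood for each gene symbol, and probes with no symbol or several stood for themselves, which left 16235 genes to test, 12367 with a symbol. Of 28 cases in which another tested probe of a named gene could be compared, the other probes all had the sign of the named one, and in 22 cases all of them passed the threshold as well. In the other 6 cases, those of Serpinf1, Ntrk2, Irf2bpl, Hdac5, Lbh and Gbp2, no other probe passed. The second probe hardly moved for Serpinf1 (0.13 against 5.92 on the log2 scale), Ntrk2 (0.23 against 1.94), Irf2bpl (0.04 against 0.96) and Gbp2 (-0.16 against -2.31). Changes moved further for Lbh (0.64 against 1.48) and Hdac5 (-0.49 and -0.58 against -0.86). The folds given for these 6 genes hold for the named probe only.

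Changes were estimated with an additive linear model of schedule and treatment in limma (22 residual degrees of freedom) with moderated variances, and p was adjusted by the Benjamini and Hochberg method over the 16235 genes, with 0.05 as the threshold. The RA contrasts are differences between schedules, the compound contrasts are differences from Mock over all schedules, and the mean of the compounds is set against Mock. The CM contrast is the difference from Mock in the same model. The Mock array of the schedule without CM and the compound arrays therefore enter it too. Interactions came from a model of each treatment with and without RA and a term for RA 24 h (11 residual degrees of freedom). Means and SD of a schedule are over the 11 matched arrays, 10 compounds and Mock. The model, the thresholds, the contrasts and the gene lists were chosen before the data were examined.

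Genes were named by a fixed rule. For RA 36 h against no RA and for the 2 RA schedules these are the 10 largest rises and falls past the threshold with the same sign in every matched treatment, and for RA 24 h against no RA, each compound and CM the 5 largest each way with the same sign in every schedule. Members of gene lists and called interactions are named in addition, and clone names are counted and not named. Folds are 2 to the power of the log2 change. For a gene detected on no array of the dim side, a fold is given as a lower bound: the mean of the bright side minus the mean, over the arrays of the dim side, of the larger of the value and that array's detection limit, the lowest value of a probe detected there.

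From general knowledge of the field, 31 gene lists were drawn up: RA response, anterior Hox, posterior Hox, shared pluripotency, naive pluripotency, primed epiblast, Activin and Nodal response, primitive streak, definitive endoderm, extraembryonic endoderm, neural ectoderm, lateral mesoderm, trophoblast, fibroblast, Hedgehog, FGF and ERK, BMP, cAMP, NF-kB and NRF2 response, heat shock, ATF4 and unfolded protein response, p53 targets, mitosis, sterol and lipid synthesis, FOXO response, glycolysis and hypoxia, calcium and NFAT response, SRF and YAP response, Wnt response, and epithelial and mesenchymal genes. Some genes are in more than 1 list. Each list was tested with limma's camera at its preset correlation of 0.01, adjusted over the 31 lists, and again with a correlation estimated from the data. Counts of members past the threshold are given over all genes and with p adjusted over the list alone.

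The method was tested on simulated data with the layout and spread of these arrays, in which some of the 16235 genes were changed. They were changed together by the same size, with independent noise and no effect of slide. Recovery after adjustment depends on how many genes change, so the rates do not carry over to comparisons in which few genes change. Changes of 1 on the log2 scale were recovered in 99.5% of cases for RA 36 h against no RA, 77% for a compound, 75.5% for CM and 94% for the mean of the compounds, with between 0 and 15 false calls in each run.

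Alternatives were the deposited log2 values, raw intensities without further background correction (quantile normalised, floored at 16 and put on a log2 scale), no filter on dim probes, detection on at least 12 arrays, each probe tested separately, slide as a random or fixed block, other comparators for the compounds, and the omission of arrays, treatments or schedules in turn. No scaling moved the median change of all genes by more than 0.1. Results on chance were checked by exchanging the labels of schedules within treatments or by splitting arrays in other ways. No group of replicate arrays was large enough for a test of outlying arrays, and no array was left out of the results.

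Software was R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8), and Python 3.11.15 with matplotlib 3.10.9 for figures.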

Results

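Total RNA from mouse epiblast stem cells (EpiSC), pluripotent cells that resemble the epiblast of the embryo after implantation, was measured on 36 bead arrays with 45281 probes each. The samples form 3 schedules. In the RA 36 h schedule, 11 samples had 5 µM retinoic acid (RA), a vitamin A derivative that drives differentiation, for 36 h and a compound or basal medium (Mock) for 24 h. In the RA 24 h schedule, 12 samples had RA for 24 h and a compound, Mock or medium conditioned by embryonic fibroblasts (CM) for 36 h. In the Mock 36 h schedule, 13 samples had no RA and a compound, Mock or CM for 24 h. The labels give how long each agent was present, and not which came first.

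Each schedule held the same 10 compounds. Rapamycin (100 nM) inhibits mTOR, PF573228 (250 nM) focal adhesion kinase, Dorsomorphin dihydrochloride (2 µM) BMP receptors and AMPK, BAY 11-7082 (25 µM) NF-kB activation, Wortmannin (50 nM) PI3 kinases and SU5402 (2 µM) FGF receptors. Forskolin (50 µM) activates adenylyl cyclase, BAPTA-AM (10 µM) binds calcium inside cells, Docetaxel (500 pM) stabilises microtubules and Purmorphamine (2 µM) activates Smoothened, the transducer of Hedgehog signals. Each compound and Mock had 1 array per schedule, and CM had 1 array with RA for 24 h and 2 without RA.

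The mean signal of an array before normalisation lay between 336 and 692.5 units, and between 37.1% and 43.1% of the probes were detected. It averaged 551 ± 79.5 (SD, n = 13) without RA, 428 ± 65.01 (n = 12) with RA for 24 h and 430.1 ± 46.6 (n = 11) with RA for 36 h. The first principal component held 54.2% of the variance. The CM arrays of the Mock 36 h schedule correlated across genes with a Pearson r of 0.989, where genes are not independent replicates. No label says whether samples came from separate cultures, so the p-values below reflect a spread between single arrays that may be technical, and the number of arrays limits the precision.

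RA for 36 h was set against no RA to ask which genes respond to RA. Hoxd4, Hoxb4, Hoxa5, Hoxd3 and Hoxb5, homeobox genes that pattern the hindbrain and neck region of the embryo, were among the 10 largest rises. Hoxd4 reached a normalised log2 intensity of 11.75 ± 0.15 (SD, n = 11) with RA against 5.00 ± 0.74 (n = 11) without. In the model, which also uses the CM arrays and from which all folds here are taken, it rose by 6.88 (SE 0.232). Nanog and Pou5f1, core factors of the pluripotency network, fell by 5.45 (SE 0.174) and 5.14 (SE 0.281) on the log2 scale, to levels 43.7-fold and 35.3-fold lower. Otx2, a regulator of the epiblast and the anterior brain, and Fgf5, a growth factor of the primed epiblast, fell by 5.71 (SE 0.253) and 5.34 (SE 0.178).

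The other large rises were those of Ednrb, an endothelin receptor of neural crest cells, at 145-fold, of Dbx1, a homeobox gene of neural tube progenitors, at 90.7-fold, of ccdc198 at 75.9-fold, of Serpinf1 at 60.3-fold and of Meis1, a partner of Hox proteins, at 47.8-fold. On the 11 arrays without RA, Ednrb was detected on 4, Hoxd4 and Dbx1 on 2, Hoxb5 on 3, Hoxa5 on 6, Meis1 on 10, Serpinf1 on 11 and each of Hoxb4, Hoxd3 and ccdc198 on 1. Where few arrays detected a gene its dim side lies near background, so its fold and its place in the order are not exact. The other large falls were those of Olig1 (26.1-fold), Fgf8 (25.5-fold), Tal2 (25.5-fold), Utf1 (24.9-fold), Slc35d3 (22.7-fold) and Wnt8a (22.4-fold). With RA, Fgf8 was detected on 1 of 11 arrays, Tal2 on 4, Wnt8a on 7, Otx2, Fgf5 and Slc35d3 on 9, Nanog and Olig1 on 10 and Pou5f1 and Utf1 on 11. These 20 genes moved the same way in all 11 treatments, with adjusted p between 7.07e-25 and 7.29e-12.

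**Figure D1:**
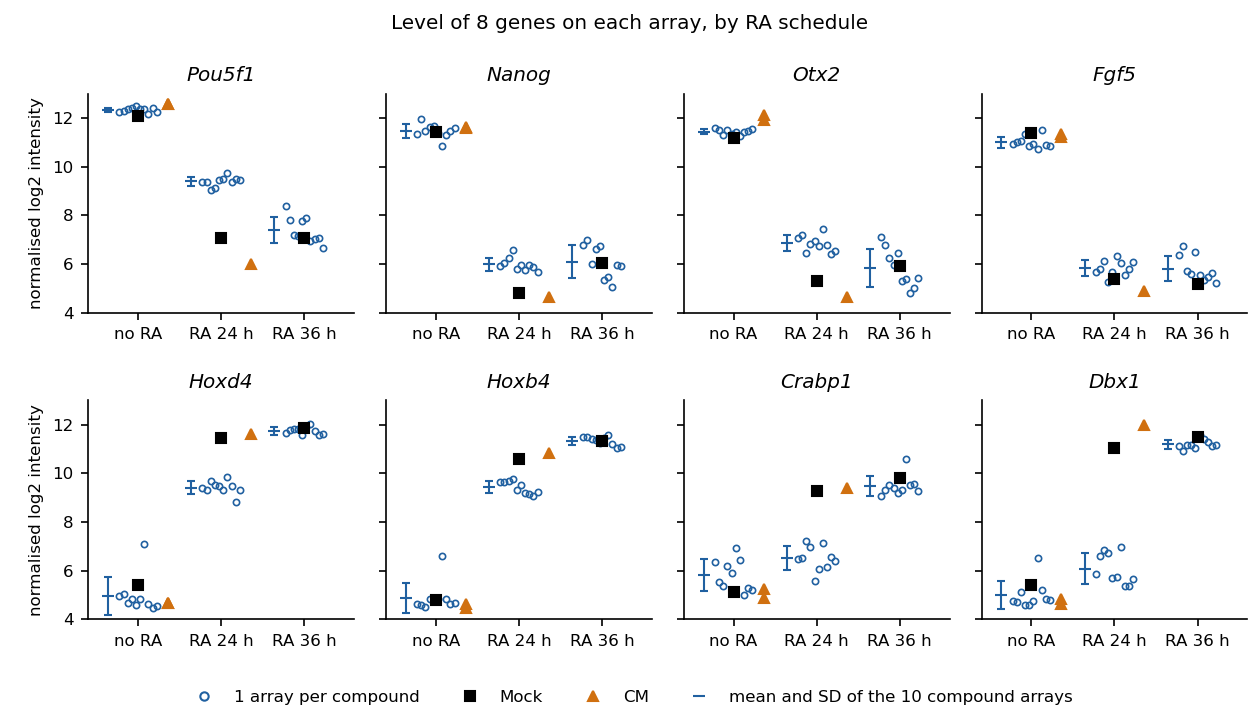
Normalised log2 intensity (vertical axes) of 8 genes on each array, by RA schedule (horizontal axes), with compounds as circles, Mock as squares, CM as triangles and bars for the mean and SD of the 10 compound arrays. Pou5f1 stood at 12.31 on average without RA and at 7.36 with RA for 36 h, while Dbx1 on the Mock and CM arrays with RA for 24 h stood at 11.03 and 11.98 against a mean of 6.08 on the compound arrays beside them.

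Among genes known to respond to RA, 12 of the 16 tested rose with RA for 36 h, 1 fell and 3 did not pass (limma camera, adjusted p = 5.02e-06, and adjusted p = 0.0286 with an estimated correlation). Crabp2, an RA-binding protein, rose by 5.39 (SE 0.163), the receptor gene Rarb by 3.49 (SE 0.0737) and Cyp26a1, an RA-degrading enzyme, by 1.43 (SE 0.154), while Rarg, another receptor gene, fell by 1.74 on the log2 scale. Of 13 anterior Hox genes 11 rose and none fell (adjusted p = 2.98e-09, and adjusted p = 0.0682 with an estimated correlation). Hoxa4 rose at least 10.1-fold and Hoxb3 at least 3.12-fold, while Hoxc4 and Hoxd1 changed by -0.16 and 0.03 without passing. In the neural ectoderm list 9 of 12 rose, such as Zic1 at least 5.24-fold, Pax6 at least 2.44-fold and Irx3 by 2.35 on the log2 scale (adjusted p = 0.00476, and adjusted p = 0.0806 with an estimated correlation).

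In the extraembryonic endoderm list 8 of 14 rose and 2 fell (adjusted p = 0.00822, and adjusted p = 0.0682 with an estimated correlation). Its risers included Lama1 by 5.03 (SE 0.157) and Col4a1 and Col4a2 by 1.18 and 1.62, which encode basement membrane proteins, and the transcription factor genes Gata6 by 1.68 and Sox7 at least 2.5-fold, while Apoa1 and Apoe fell by 0.90 and 0.76. In the list of epithelial and mesenchymal genes 8 of 11 rose and 3 fell (adjusted p = 0.00822, and adjusted p = 0.0806 with an estimated correlation). The mesenchymal genes Zeb1 and Vim rose by 3.25 and 2.41 and Cdh2 at least 2.6-fold, Cdh1 and Cldn6 of epithelial junctions fell by 1.44 and 1.11, Snai1 fell by 0.49, and the epithelial keratin genes Krt8 and Krt18 rose by 0.95 and 1.13. The BMP response list had 7 risers, among them Id1 by 2.20 (SE 0.121), and 1 faller, Hey1 by 0.40, of 8 (adjusted p = 0.00822, and adjusted p = 0.0806 with an estimated correlation).

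Of 11 genes that respond to the regulators SRF and YAP 8 rose, such as Ankrd1 by 2.22, Acta2 by 1.81 and Myl9 by 1.75 (adjusted p = 0.00242, and adjusted p = 0.23 with an estimated correlation). Of 6 calcium and NFAT response genes 4 rose, such as Egr3 at least 1.73-fold and Rcan1 by 0.69 (adjusted p = 0.0256, and adjusted p = 0.296 with an estimated correlation). Fibroblast markers moved with RA as well. Of 9 tested 7 rose, among them Col1a2 by 3.24 (SE 0.162), Col1a1 by 1.71 (SE 0.187) and Dcn by 0.59, and Thy1 fell by 2.78 (adjusted p = 0.0172, and adjusted p = 0.151 with an estimated correlation).

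Of 10 pluripotency genes shared by naive and primed cells 7 fell, such as Tdgf1, at least 6.82-fold lower, and Esrp1, which fell by 2.59 on the log2 scale, while Sox2, a factor of pluripotent and neural cells, rose by 1.18 (adjusted p = 0.00143, and adjusted p = 0.177 with an estimated correlation). Of 11 primed epiblast genes 9 fell, among them the methyltransferase gene Dnmt3b, which fell by 2.66, and Pim2, which fell by 3.89, while the Wnt modulator Sfrp2 rose in all 11 treatments (adjusted p = 1.3e-05, and adjusted p = 0.0576 with an estimated correlation). In the list of Activin and Nodal response genes 7 of 9 fell, such as Cer1, at least 2.29-fold lower, Lefty1, which fell by 0.89, and Nodal, which fell by 1.20 (adjusted p = 0.00509, and adjusted p = 0.177 with an estimated correlation). Of 11 primitive streak genes 8 fell, such as Eomes, which fell by 3.18 (SE 0.184), and Gsc, at least 4.41-fold lower, and Wnt3a rose in all 11 treatments (adjusted p = 0.00476, and adjusted p = 0.177 with an estimated correlation). Of 13 glycolysis and hypoxia genes 10 fell, such as Egln3, which fell by 1.88, and Ldha, which fell by 1.06, while Slc2a1, Vegfa and Pgk1 rose by 1.04, 1.02 and 0.27 (adjusted p = 0.0256, and adjusted p = 0.432 with an estimated correlation).

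The other 17 lists did not pass as lists. Naive pluripotency genes split, with 2 of 9 higher, Esrrb by 1.32 and Klf5 by 0.57, and 6 lower, such as Fgf4, at least 3.36-fold lower (adjusted p = 0.325). In the FGF and ERK response list 7 of 15 rose, such as Dusp5 by 2.07, and 6 fell, such as Etv4, which fell by 2.35, and Spry4, which fell by 1.73 (adjusted p = 0.768). Definitive endoderm genes had 4 risers, such as Cxcr4 by 3.12, and 4 fallers, such as Foxa2, which fell by 1.26, of 10 (adjusted p = 0.93). Of 5 posterior Hox genes Hoxc9 rose by 0.40 while Hoxa13 and Hoxc10 fell by 0.41 and 0.38 (adjusted p = 0.745). Risers and fallers numbered 4 and 0 of 8 for lateral mesoderm (adjusted p = 0.0603), 2 and 1 of 7 for trophoblast (0.726), 2 and 0 of 3 for Hedgehog response (0.209) and 1 and 3 of 9 for Wnt response (0.45). They numbered 3 and 3 of 8 for cAMP response (0.93), 3 and 2 of 8 for NF-kB response (0.93), 3 and 3 of 7 for NRF2 response (0.624), 2 and 2 of 10 for heat shock (0.822) and 4 and 6 of 16 for ATF4 and unfolded protein response (0.662). They numbered 6 and 1 of 13 for p53 targets (0.394), 5 and 3 of 15 for mitosis (0.726), 2 and 6 of 13 for sterol and lipid synthesis (0.325) and 6 and 3 of 13 for FOXO response (0.662). Adjusted over the list alone, the counts of all 31 lists were those over all genes, except 4 in place of 3 fallers for mitosis. The sign of the median differed from that of the mean or the test for definitive endoderm, trophoblast, cAMP, NF-kB and ATF4.

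**Figure D2:**
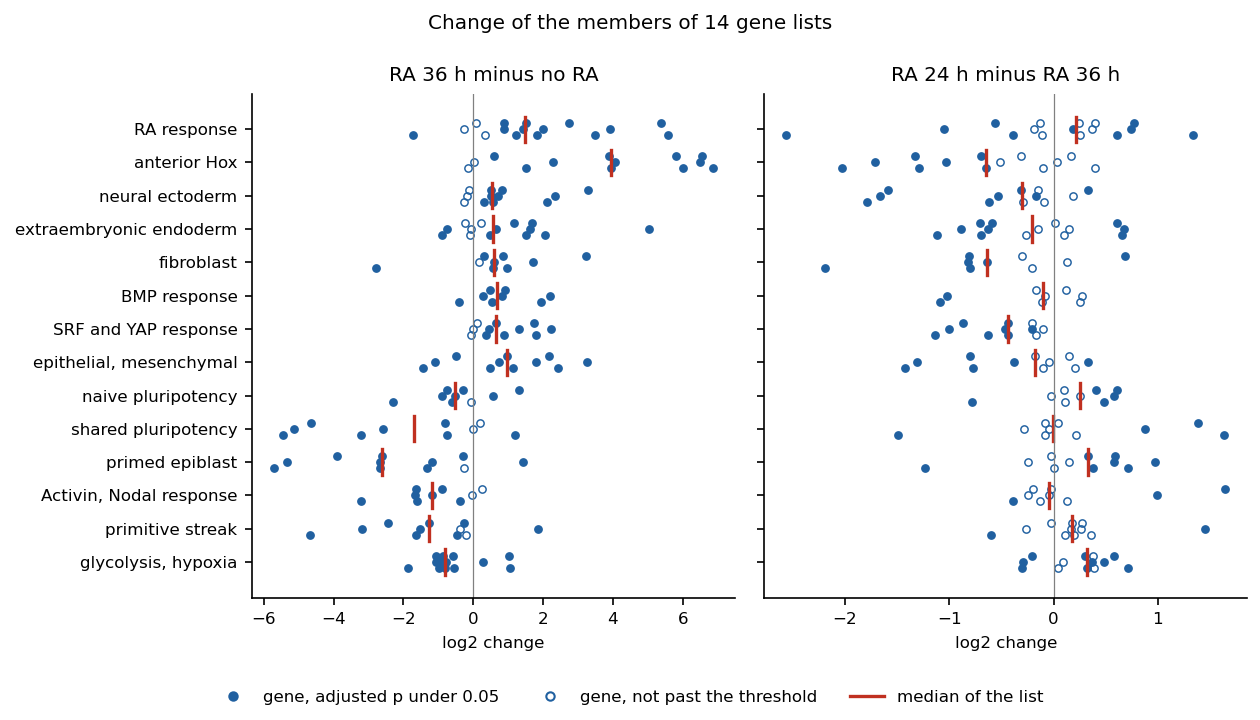
Log2 change (horizontal axes) of each tested member of 14 gene lists (vertical axis), on the left for RA 36 h against no RA and on the right for RA 24 h against RA 36 h, with filled points for adjusted p under 0.05, open points for the others and a red bar for the median of the list. On the left the median of the anterior Hox genes is 3.95 and that of the primed epiblast genes is -2.62.

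In all, 9269 of 16235 genes passed limma's moderated test, 4346 higher and 4923 lower with RA for 36 h, and 791 rises and 719 falls were of at least 1 on the log2 scale. The same sign in all 11 treatments was shown by 1979 of the risers and 1989 of the fallers. The schedules lay on different slides, except that 1 slide held the Mock array without RA beside 5 compound arrays with RA for 36 h. Within that slide 2464 genes passed, 2341 of them among the 9269, but the side without RA is that 1 array and RA goes there with compound against Mock. With slide as a fixed block and RA or not in place of schedule 2047 passed, resting on the same array.

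RA for 24 h was set against RA for 36 h to ask what differs between the schedules, in which the time with a compound was also 36 h against 24 h. Dbx1 fell by 4.38 (SE 0.491) on the log2 scale and was 20.8-fold lower with RA for 24 h, and Crabp1, an RA-binding protein, 5.91-fold lower. Pou5f1 was 3.11-fold higher in the model (SE 0.281 on the log2 scale), which also uses the CM arrays, and its means over the 11 matched treatments were 9.18 and 7.36. Glra2, a glycine receptor subunit, was 7.81-fold higher, and Upp1, an enzyme of uridine breakdown, 5.34-fold higher. The Mock and CM arrays of the RA 24 h schedule stood apart from its compound arrays for these genes. Pou5f1 averaged 9.39 on the 10 compound arrays and stood at 7.07 on Mock and 6.01 on CM, and Glra2 averaged 9.60 and stood at 6.48 and 7.55.

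The other large rises were those of B3gnt7 (4.42-fold), Wnt8a (4.06-fold), Ntrk2 (3.83-fold), Cyp2b23, Slc27a2, Plppr1 and Gtsf1l, and the other large falls were those of Megf10 (7.75-fold), Cyp1b1 (4.79-fold), Col1a2 (4.56-fold), Vit, Anxa1, Arg1, Ncald and Nsg2. These 20 genes had the same sign in all 11 treatments. On the dimmer side Cyp2b23 was detected on 2 of 11 arrays, Nsg2 on 4, Slc27a2 on 6, Wnt8a and Gtsf1l on 7, Megf10 and Ncald on 8, Plppr1 on 9, Anxa1 on 10 and the others on all. For Dbx1, Megf10, Glra2 and Pou5f1 the smallest of the 11 differences, -0.48, -0.03, 0.14 and 0.01, were those between the Mock arrays.

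Of 13 anterior Hox genes 7 were lower with RA for 24 h, such as Hoxd4 by 2.03 (SE 0.232) and Hoxb4 by 1.71 (SE 0.191) on the log2 scale, with 8 lower and 1 higher adjusted over the list alone (adjusted p = 0.00496, and adjusted p = 0.477 with an estimated correlation). The Mock and CM arrays of this schedule, at 11.44 and 11.60 for Hoxd4, stood above its compound arrays, whose mean was 9.41. Of 12 neural ectoderm genes 7 were lower, such as Irx3, which fell by 1.79, and Pax6, which fell by 1.59, and Sox3 was higher by 0.33 (adjusted p = 0.0062, and adjusted p = 0.212 with an estimated correlation). Of 11 SRF and YAP response genes 8 were lower, such as Ankrd1, which fell by 1.13 (adjusted p = 0.000805, and adjusted p = 0.399 with an estimated correlation). Of 9 fibroblast markers 5 were lower, such as Col1a2, which fell by 2.19 (SE 0.162), and Thy1 was higher by 0.68, with 6 lower adjusted over the list alone (adjusted p = 0.00725, and adjusted p = 0.212 with an estimated correlation). On these 3 lists too the compound arrays lay below the 1 Mock array with RA for 24 h, with median differences of -0.28, -0.58 and -0.79, against -0.05, 0.04 and 0.05 with RA for 36 h. Among RA response genes 5 of 16 were higher, such as Cyp26a1 by 1.34, and 4 lower (adjusted p = 0.757). Of the pluripotency genes Sox2 fell by 1.49 and Utf1 rose by 1.38, in a list with 3 of 10 higher and 1 lower (adjusted p = 0.791). Utf1 averaged 7.93 on the compound arrays with RA for 24 h and stood at 5.87 on Mock and 5.23 on CM, against 6.06 on Mock with RA for 36 h, so the Mock arrays do not show its rise.

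In all, 6559 genes differed, 3538 higher and 3021 lower with RA for 24 h, with 135 rises and 169 falls of at least 1 on the log2 scale. The same sign in all 11 treatments was shown by 965 and 788. No slide held both schedules, so slide and schedule cannot be told apart here, and with slide as a random block 4148 genes passed. On the 10 compounds alone, without the Mock and CM arrays, 6657 passed.

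RA for 24 h was also set against no RA. Hoxa5 rose 91.7-fold, by 6.52 (SE 0.193) on the log2 scale, ccdc198 59.8-fold, Olfml3, a secreted matrix protein, 46.3-fold, Ednrb 46.1-fold and Grifin 39.5-fold. Nanog fell by 5.73 (SE 0.167), Fgf5 by 5.37 (SE 0.171) and Otx2 by 5.00 (SE 0.242), and Olig1 and Slc35d3 were 25.5-fold and 25.4-fold lower. On the 11 arrays without RA, ccdc198 was detected on 1, Grifin on 2, Ednrb on 4, Olfml3 on 5 and Hoxa5 on 6, and with RA for 24 h Slc35d3 was detected on 9 and Nanog on 10.

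Of 16 RA response genes 13 rose, such as Rarb by 3.68, and 3 fell, namely Rarg, Cyp26b1 and Rdh10 (adjusted p = 4.04e-06, and adjusted p = 0.0265 with an estimated correlation). Of 11 primed epiblast genes 9 fell and none rose (adjusted p = 6.2e-06, and adjusted p = 0.0458 with an estimated correlation). Another 6 lists passed with the preset correlation. Of 13 anterior Hox genes 11 rose and Hoxc4 fell by 0.48 (adjusted p = 3.27e-08, and adjusted p = 0.129 with an estimated correlation), and of 10 shared pluripotency genes 7 fell (adjusted p = 0.000226, and adjusted p = 0.194 with an estimated correlation). Activin and Nodal response genes fell in 7 of 9 cases (adjusted p = 0.0121, and adjusted p = 0.275 with an estimated correlation). Of 11 primitive streak genes 6 fell while Lhx1 and Wnt3a rose by 1.07 and 1.25 (adjusted p = 0.0452, and adjusted p = 0.296 with an estimated correlation). Of 14 extraembryonic endoderm genes 8 rose and 2 fell (adjusted p = 0.0459, and adjusted p = 0.184 with an estimated correlation), and of 6 calcium and NFAT response genes 4 rose (adjusted p = 0.0216, and adjusted p = 0.275 with an estimated correlation). For these 8 lists the counts adjusted over the list alone were the same. Neural ectoderm genes (5 higher and 1 lower of 12, adjusted p = 0.153) and fibroblast markers (5 higher and 2 lower of 9, adjusted p = 0.584) did not pass as lists.

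In all, 10126 genes differed, 4772 higher and 5354 lower, with 606 rises and 498 falls of at least 1 on the log2 scale, and 1807 and 1634 had the same sign in all 11 treatments. No slide held both of these schedules either.

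Docetaxel was compared with Mock over the 3 schedules, and 14 genes passed, 11 higher and 3 lower, of which 9 and 3 had the same sign in every schedule. Il11, a cytokine of the interleukin 6 family, rose 3.8-fold, by 1.93 (SE 0.335) on the log2 scale. Myl4, a myosin light chain, rose 2.42-fold, Pde4b, a cAMP phosphodiesterase, 2.31-fold, Txnip, an inhibitor of thioredoxin, 2.04-fold and Irf2bpl 1.95-fold. Tnfaip3, a brake on NF-kB signalling, fell by 0.98 (SE 0.183), the histone deacetylase gene Hdac5 by 0.86 (SE 0.151) and the protease inhibitor gene Cst3 by 0.68 (SE 0.113). Adjusted p for these 8 genes lay between 0.017 and 0.0487 (n = 3 arrays a side, limma).

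**Figure D3:**
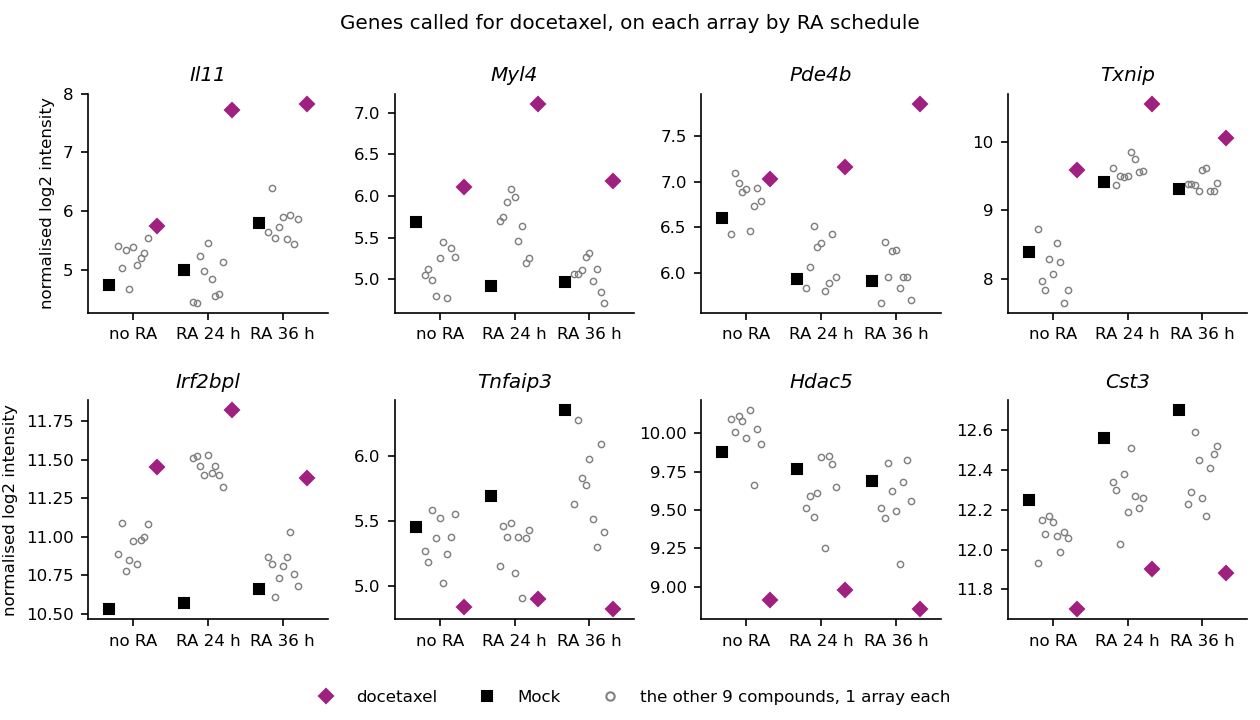
Normalised log2 intensity (vertical axes) of the 8 genes named for Docetaxel on each array, by RA schedule (horizontal axes), with diamonds for Docetaxel, squares for Mock and circles for the other 9 compounds. Hdac5 and Cst3 were lower with Docetaxel than on the Mock array in each of the 3 schedules.

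Of 8 cAMP response genes Pde4b rose, 2 rose adjusted over the list alone, and Pde4d changed by 1.64 (SE 0.377, adjusted p = 0.0914). The list passed as a whole (adjusted p = 0.000262, and adjusted p = 0.0286 with an estimated correlation), with Crem at -0.16 against it. Of 8 NF-kB response genes Tnfaip3 fell, 2 fell adjusted over the list alone, and Cxcl1 changed by -1.49 (SE 0.349, adjusted p = 0.0957), with Ccl20 at 0.42 the other way (list adjusted p = 0.00238, and adjusted p = 0.0286 with an estimated correlation). No single gene passed among 11 SRF and YAP response genes, 4 fell adjusted over the list alone, and Myl9 changed by -1.11 (list adjusted p = 0.000262, and adjusted p = 0.274 with an estimated correlation). None passed among 9 fibroblast markers, 3 fell adjusted over the list alone, and Col3a1 changed by -0.70 (list adjusted p = 0.0109, and adjusted p = 0.131 with an estimated correlation). These 2 lists were also lower over all 10 compounds than on the Mock array with RA for 24 h, with median differences of -0.58 and -0.79 (0.04 and 0.05 with RA for 36 h, and -0.20 and -0.05 without RA), in means that include Docetaxel and share its Mock arrays. In the lists nearest to the action of Docetaxel, none of 15 mitosis genes (adjusted p = 0.402) and none of 13 p53 targets (adjusted p = 0.242) passed, with 0 and 1 lower adjusted over the list alone.

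The Docetaxel array without RA held low levels of transcripts that RA raises, such as Hoxb4 at 6.61 against 4.67 ± 0.128 (SD, n = 12) on the other arrays of its schedule. Without that array 54 genes passed for Docetaxel, 10 of them among the 14. Without the RA 36 h, RA 24 h or Mock 36 h schedule 3, 0 and 29 genes passed, and with slide as a fixed block 3 passed, none among the 14. With that block the cAMP list had adjusted p = 0.239 and the NF-kB list adjusted p = 0.523. On the deposited log2 values 30 passed, without a filter on dim probes 9, and against the mean of the other 9 compounds 38, of which 11, 9 and 9 were among the 14.

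For the other 9 compounds against Mock, limma called 0 genes each at an adjusted p under 0.05. At an unadjusted p under 0.05 the count was 1124 for Rapamycin, 848 for PF573228, 820 for Dorsomorphin dihydrochloride, 727 for BAY 11-7082, 1064 for Forskolin, 1135 for BAPTA-AM, 1223 for Wortmannin, 1210 for Purmorphamine and 983 for SU5402. With no change at all, a share of 0.05 of the 16235 genes would be due there. Unadjusted counts, here and below, are therefore not counts of genes that respond. In simulated data of this layout, 77% of genes changed by 1 on the log2 scale and 8% of those changed by 0.5 were recovered. There a set of genes changed together without slide effects, so these rates do not say what would be found if few genes changed. Ptch1, the Hedgehog receptor and target gene, changed by 0.69 (SE 0.253) with Purmorphamine, higher in 3 of 3 schedules, with adjusted p = 0.564, and was the 1 of 3 Hedgehog response genes to pass adjusted over the list alone.

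Of the other lists nearest to the targets of these 9 compounds none had a member past the test, over all genes or adjusted over the list alone. The adjusted p of the list was 0.162 for sterol and lipid synthesis and 0.265 for glycolysis with Rapamycin, 0.177 for SRF and YAP with PF573228, 0.493 for BMP with Dorsomorphin dihydrochloride, where Id1 changed by -0.52 (adjusted p = 0.963), and 0.15 for Hedgehog with Purmorphamine. It was 0.986, 0.749, 0.856 and 0.94 for NF-kB, NRF2, heat shock and ATF4 with BAY 11-7082, 0.936 for cAMP with Forskolin, 0.635 for calcium and NFAT with BAPTA-AM, 0.702 for FOXO with Wortmannin and 0.938 for FGF and ERK with SU5402.

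Other lists passed with the preset correlation and none of them with an estimated one, and none of their members passed over all genes. These comparisons share the same 3 Mock arrays and are not independent of each other. Anterior Hox genes were lower with Rapamycin, PF573228, Dorsomorphin dihydrochloride, BAY 11-7082, Forskolin and Purmorphamine, with medians from -0.48 to -0.31 and adjusted p of 0.652, 0.51, 0.546, 0.797, 0.617 and 0.45 in that order with an estimated correlation. Their median difference from Mock lay between -1.16 and -0.77 for all 10 compounds with RA for 24 h, where the Mock array stands apart, between -0.27 and 0.14 with RA for 36 h and between -0.28 and 0.65 without RA. Primed epiblast genes were higher with Rapamycin and BAPTA-AM (0.356 and 0.372 with an estimated correlation), and shared pluripotency genes were higher with PF573228 (0.51). P53 targets were lower with Rapamycin and Dorsomorphin dihydrochloride (0.356 and 0.546), SRF and YAP response genes with Wortmannin and Purmorphamine (0.561 and 0.45) and primitive streak genes with BAPTA-AM and Purmorphamine (0.372 and 0.45). Lateral mesoderm genes and fibroblast markers were lower with BAPTA-AM (0.248 each). Over all 10 compounds the shared pluripotency, primed epiblast, p53, lateral mesoderm and primitive streak lists had median differences of 0.365, 0.215, -0.28, -0.28 and 0.06 from the 1 Mock array with RA for 24 h. They were 0.07, 0.09, 0.16, 0.07 and 0.02 with RA for 36 h and 0.05, 0.20, -0.22, -0.33 and -0.70 without RA, so these calls too can follow single Mock arrays. Adjusted over the list alone, 1 primed epiblast gene rose and 1 p53 target fell with Rapamycin and 3 fibroblast markers fell with BAPTA-AM.

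The mean of the 10 compounds was set against Mock to ask what compounds share. Dbx1 was 4.94 lower on the log2 scale on compound arrays than on Mock with RA for 24 h, Megf10 3.33 lower and Cxcl12, a chemokine, 4.13 higher, whereas with RA for 36 h they differed by -0.31, 0.06 and 0.25. These differences were looked at after the Mock array was seen to stand apart and rest on that 1 array per schedule, so they describe and do not test. Over all schedules limma called 0 genes, 1431 at an unadjusted p under 0.05, with a smallest adjusted p of 0.0713.

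Anterior Hox genes, SRF and YAP response genes and fibroblast markers were lower as lists in that mean (adjusted p = 0.0107, 0.0165 and 0.033, and adjusted p = 0.427 each with an estimated correlation). Within schedules, again against 1 Mock array each, their median differences were -0.99, -0.58 and -0.79 with RA for 24 h, -0.09, 0.04 and 0.05 with RA for 36 h and -0.03, -0.20 and -0.05 without RA. Hoxb4 differed by -1.17, 0.01 and 0.10 in the 3 schedules in that order. None of their members passed over all genes, and 2 fibroblast markers fell adjusted over the list alone. Hoxd4 changed by -0.87 (SE 0.335, adjusted p = 0.446) and Col3a1 by -0.49 (SE 0.124, adjusted p = 0.225). Without the Mock array of the RA 36 h schedule 60 genes passed, and without that of the Mock 36 h schedule 6.

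CM was set against Mock, basal medium, to ask what factors from fibroblasts change. Fgfbp1, a carrier of FGF, fell by 2.42 (SE 0.19) on the log2 scale and was 5.36-fold lower in CM, and the membrane-binding protein gene Anxa3 5.67-fold lower. Lgals3, a galectin, Gbp2, an interferon-induced GTPase, and Plaur, the urokinase receptor, were 5.18-fold, 4.97-fold and 4.83-fold lower. Stc1, a secreted glycoprotein hormone, was 4.14-fold higher, by 2.05 (SE 0.44), followed by Emilin2 (2.92-fold), Brinp2 (2.87-fold), Lbh (2.78-fold) and Lmo2 (2.76-fold). Lmo2 was higher by 2.93 with RA for 24 h and by 0.23 without RA.

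Of 8 NF-kB response genes 3 fell in CM and 4 adjusted over the list alone, such as Cxcl1, a chemokine, which fell by 1.77 (adjusted p = 1.97e-05, and adjusted p = 0.00457 with an estimated correlation). Of 11 epithelial and mesenchymal genes 4 fell and 5 adjusted over the list alone. Krt8 fell by 1.36 (SE 0.149), Zeb2 fell by 0.85 and Fn1 fell by 0.59, so both kinds of gene were among them (adjusted p = 1.89e-05, and adjusted p = 0.00665 with an estimated correlation). Of 7 trophoblast genes Tfap2c fell, by 1.37, and 3 adjusted over the list alone (adjusted p = 0.00315, and adjusted p = 0.0284 with an estimated correlation). These 3 of the 10 lists past the preset test held with an estimated correlation. With slide as a fixed block their adjusted p was 0.0273, 0.00021 and 0.0539 in that order. The mean of the compounds differed from the 1 Mock array without RA by medians of -0.19, -0.04 and -0.34 on these lists. With RA for 24 h the medians were 0.002, -0.28 and 0.02, and with RA for 36 h 0.15, 0.20 and -0.04, so single Mock arrays can enter these calls.

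Of 11 SRF and YAP response genes 4 fell, such as Ankrd1, which fell by 1.69, and Ccn1, which fell by 1.66, and 6 adjusted over the list alone (adjusted p = 1.89e-05, and adjusted p = 0.0916 with an estimated correlation). The mean of the compounds also lay below the 1 Mock array on this list, with median differences of -0.58 with RA for 24 h and -0.20 without RA (0.04 with RA for 36 h). Naive pluripotency genes had 2 fallers, Klf5, which fell by 1.68 (SE 0.174), and Klf2, which fell by 1.37, and Dppa5a rose by 1.09, with 3 fallers and 1 riser adjusted over the list alone (adjusted p = 0.00726). Primitive streak genes had 2 fallers, Gsc, which fell by 1.31, and Fgf8, and 3 adjusted over the list alone (adjusted p = 0.000534), but the mean of the compounds also lay below the 1 Mock array without RA on this list, with a median difference of -0.70. FGF and ERK response genes had 2, Dusp5, which fell by 1.19, and Ccnd1, which fell by 0.68, and 4 adjusted over the list alone (adjusted p = 0.0115). NRF2 response and sterol synthesis genes had 1 each on both counts, Nqo1, which fell by 0.84, and Cyp51, which fell by 0.36 (adjusted p = 0.0115 and 0.0395). For these last 5 lists adjusted p = 0.0916 with an estimated correlation. Glycolysis and hypoxia genes were higher, with Pfkl up by 0.88 and Pgk1 by 0.54, and 8 higher and 1 lower adjusted over the list alone (adjusted p = 0.000628, and adjusted p = 0.188 with an estimated correlation). Among 9 fibroblast markers Dcn fell by 0.99, and 3 fell adjusted over the list alone (adjusted p = 0.0614).

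In all, 540 genes differed in CM, 183 higher and 357 lower, and 148 and 303 of them had the same sign in both schedules with CM. CM and Mock shared no slide, and with slide as a fixed block and RA or not in place of schedule 61 genes passed, 42 of them among the 540. The count was 870 without the CM array with RA, 274 and 354 without CM replicate 1 and 2 of the Mock 36 h schedule, and 185 without the Mock array of that schedule.

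An interaction model asked for each compound whether its change from Mock differed with and without RA. Lclat1 was called for Dorsomorphin dihydrochloride, with an effect lower by 1.82 (SE 0.249, adjusted p = 0.0398) on the log2 scale with RA, and for BAY 11-7082, lower by 1.81 (SE 0.249, adjusted p = 0.0438). Cntn2, an adhesion molecule of neurons, was called for Forskolin, with an effect higher by 2.26 (SE 0.279, adjusted p = 0.0116) with RA. On the Mock arrays Lclat1 stood at 5.71 and 5.64 with RA for 36 h and 24 h and was not detected without RA, and Cntn2 stood at 6.12 without RA and was not detected with RA. The arm without RA is 1 compound array against that 1 Mock array, so all 3 calls rest on that array. Each has Mock values at background, without RA for Lclat1 and with RA for Cntn2, and none of the 3 sizes is exact. For the other 7 compounds limma called 0 genes, with 1300 (Rapamycin), 1082 (PF573228), 1134 (BAPTA-AM), 1479 (Docetaxel), 1035 (Wortmannin), 1013 (Purmorphamine) and 1263 (SU5402) at an unadjusted p under 0.05. In simulated data of this layout 67.5% of genes that differed by 2 and 0.5% of those that differed by 1 on the log2 scale were recovered. There too a set of genes changed together, and 1 Mock array without RA serves all 10 tests.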

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

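The compound comparisons within each RA schedule and the tests of the patterns below were chosen after the results were seen, while the interaction tests and the exchanges of labels were planned.

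The Lclat1 response to Dorsomorphin dihydrochloride and BAY 11-7082 differed with RA by -1.823 and -1.809 on the log2 scale, and the Cntn2 response to Forskolin by 2.259. The Mock array without RA serves all 3 contrasts, with Lclat1 at 4.35, not detected, against 5.71 and 5.64 on the Mock arrays with RA, and Cntn2 at 6.12 against 4.50 and 4.41, not detected, so none of the 3 sizes is exact. With the deposited log2 values BAY 11-7082 had 0 calls, Dorsomorphin dihydrochloride 2 and Forskolin 1, none of them these genes. The gap between compound arrays and Mock differed between RA 24 h and RA 36 h for 232 genes, 117 higher and 115 lower, such as Dbx1 by -4.63 and Cxcl12 by 3.89. That count rests on 1 Mock array per schedule and was made because the array was seen to stand apart, so it restates that and tests no cause.

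With RA for 24 h, Mock and CM stood apart from the 10 compound arrays at 862 genes. Dbx1, for example, stood at 11.03 and 11.98 against a mean of 6.08. Of the 862 genes 843 differed in the direction of RA for 36 h. Gap and direction were both measured from the same mean of the RA 24 h compound arrays. Any trait of those compound arrays would thus make the signs match, so the 843 are no separate support. A position effect common to all slides is argued against. Mock and CM arrays of the other schedules, in the same position, had slopes along these genes of at most 0.0335. Only the RA 36 h Mock array among them had RA, with a slope of 0.0313. Without RA, genes that RA raises, such as Dbx1, lie near background and could show little shift. For those genes the argument rests on that 1 array. The slopes of the RA 24 h Mock and CM arrays themselves, 0.893 and 1.11, are high by construction, since the genes were chosen on these 2 arrays. A position effect on the slides of these 2 arrays alone cannot be told apart from other causes. Whether the 2 arrays hold RA 36 h samples under a wrong label cannot be told apart from other causes, since they lie at 0.847 and 0.746 on an axis where RA 24 h compound arrays span -0.129 to 0.165 and RA 36 h ones 0.97 to 1.03. A candidate explanation is that compounds, or what they were dissolved in, slow the response to RA if they were given before it, an order inferred from the durations. It cannot be told apart either, since the 681 genes between compounds and Mock at RA 24 h and 1 at RA 36 h each rest on 1 Mock array and restate the pattern.

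On the Docetaxel array without RA, 67 of 75 genes strongly raised by RA lay above the mean of the other arrays of the schedule. Hoxd4 stood at 7.09 against 4.77 ± 0.265 (SD, n = 12), while Pou5f1 stood at 12.36 against 12.35. RNA from an RA 36 h sample may be present on this array. Its excess over the mean of the other arrays followed the rise with RA for 36 h across genes. There r was 0.917, against at most 0.631 for another array, and genes are not independent replicates. The median excess was 3.5% of that rise. For the rise with RA for 24 h, over 53 genes, r was 0.789 against at most 0.63, at a median excess of 4.06% of that rise. Which RA schedule such RNA would come from was not tested. RA that reached the culture cannot be told apart from such RNA. The excess of Rarb was 1.06% of its rise with RA for 36 h (SD of the other arrays 1.85%). That of Cyp26a1 was -4.81% (SD 14.8%). An effect of Docetaxel cannot be told apart either, since on the RA 36 h Docetaxel array the same genes were higher by a median of 0.249 against at most 0.0264 for another compound.

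Labels of the schedules were exchanged within treatments in 99 random ways beside the real one. For RA 36 h against no RA 1 of 100 splits, the real one, reached 9269 genes, the next highest with 7796. For RA 24 h against RA 36 h 1 of 100 reached 6559, the next with 4779. For RA 24 h against no RA 1 of 100 reached 10126, the next with 8543. The counts thus go with the real labels, but each exchange also exchanged slides. A difference of slide or culture would do the same, so these splits do not show that RA is the source. The next highest each came from exchanging the labels of 1 treatment. For the number of lists chance cannot be excluded, with 6 of 100 splits reaching the real 14 (highest other 16), 23 of 100 reaching 4 (highest other 8) and 25 of 100 reaching 8 (highest other 13). The split with 16 exchanged only Dorsomorphin dihydrochloride and Docetaxel. Most of the RA contrast stayed in it, so such splits decide little about chance.

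For each compound the 6 arrays allow 10 splits, too few for a share under 0.05. For Docetaxel 1 of 10 splits reached the real 14 genes (highest other 13) and 3 of 10 the real 4 lists (highest other 5). For the other 9 compounds the real count was 0, which all 10 splits reach, and the highest other was 1 for Rapamycin, Dorsomorphin dihydrochloride, Wortmannin and Purmorphamine, 2 for PF573228, Forskolin and BAPTA-AM, 3 for SU5402 and 0 for BAY 11-7082. For CM, 10 splits are again too few: 2 of 10 reached the real 540 genes (highest other 637) and 3 of 10 the real 10 lists (highest other 14). The split with 637 puts both CM arrays without RA and the RA 36 h Mock array on a side, and both RA 24 h arrays on the other.

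For the mean of the compounds, 3 random arrays took the place of Mock, and 100 of 100 splits reached the real 0 genes, the highest with 42, while 14 of 100 reached the real 3 lists, the highest with 6. The split with 42 genes holds the RA 24 h Mock array and 2 Docetaxel arrays, and what gave that count was not tested.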

How the results depend on the processing

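Tests within the shared slide, with slide as a fixed block for single compounds and CM, without the Docetaxel array of the Mock 36 h schedule, on slide mates, with slide as a fixed block for lists, on 10 compounds only and on 1 schedule alone were chosen after the results were seen, and the others were planned.

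The named RA genes, such as Hoxd4, Nanog and Pou5f1, kept sign and threshold in every alternative in which they were followed. Among the RA contrasts, slide as a fixed block was available for RA 36 h versus Mock 36 h only, so the genes of the other contrasts did not face it. Detection on at least 12 arrays was not followed for RA 24 h versus Mock 36 h. The alternatives also left out each probe tested separately, where the second probes of Serpinf1 and Ntrk2 did not pass. The RA 36 h versus Mock 36 h count of 9269 lay between 8827 and 9236 with treatments left out, and fell to 2047 with slide as a fixed block (1951 shared) and 2464 within the slide that holds both (2341 shared), both resting on 1 Mock array without RA. RA 24 h versus RA 36 h (6559) lay between 5941 and 6738, with 4148 for slide as a random block, since no slide holds both schedules, and RA 24 h versus Mock 36 h (10126) between 9636 and 9995.

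The Docetaxel genes were less steady, and the cause was not tested. Against 14, the count was 30 with the deposited log2 values (11 shared), 9 without a filter on dim probes, where more genes are tested, 3 with slide as a fixed block (none shared), and 0 to 29 with a schedule left out (0 without RA 24 h, 3 without RA 36 h, 29 without Mock 36 h). It was 54 without the Docetaxel array of the Mock 36 h schedule (10 shared), 38 against the mean of the other 9 compounds (9 shared) and 117 against the 4 slide mates (10 shared). Il11, Hdac5 and the other 6 named genes passed in none of 8 cases with slide as a fixed block, and in 6 of 24 with a schedule left out, always with the same sign.

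For compounds with 0 genes, Rapamycin had 1 without background correction and 1 with slide as a fixed block. PF573228 had 1 with slide as a fixed block and 0 to 1 with a schedule left out (1 without Mock 36 h), Wortmannin 1 and 0 to 1 (1 without RA 36 h). Purmorphamine had 2 with the deposited log2 values, 3 with slide as a fixed block and 0 to 1 with a schedule left out. SU5402 had 2 with the deposited values, and 1 each without background correction, without a filter and with slide as a fixed block.

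CM had 61 with slide as a fixed block (42 shared) and 185 to 870 with an array left out. These were 185 without Mock of Mock 36 h, 274 and 354 without CM replicate 1 and 2 of that schedule, 393 and 654 without Mock of RA 24 h and RA 36 h, and 870 without CM of RA 24 h. The deposited values gave 579, split 272 higher and 307 lower against 183 and 357, with 410 shared, and the Mock 36 h schedule alone 734 (292 shared). Of the 10 named CM genes 2 passed with slide as a fixed block.

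The mean of the compounds, 0 genes, had 3 with the deposited values, 9 without background correction, 7 without a filter, 4 with detection on 12 arrays, 2 with slide as a fixed block and 0 to 60 with a Mock array left out (60 without RA 36 h Mock, 6 without Mock 36 h Mock).

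Of the interactions, the deposited values gave 7 for Rapamycin, 2 for PF573228, 2 for Dorsomorphin dihydrochloride (both higher, where Lclat1 was lower), 0 for BAY 11-7082, 9 for BAPTA-AM, 8 for Docetaxel, 2 for Purmorphamine and 2 for SU5402. Without a filter Rapamycin had 1.

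With an estimated correlation 1 of 14 lists remained for RA 36 h versus Mock 36 h, 0 of 4 for RA 24 h versus RA 36 h, 2 of 8 for RA 24 h versus Mock 36 h, 2 of 4 for Docetaxel, 3 of 10 for CM and 0 of 3 for the mean of the compounds. For RA 36 h versus Mock 36 h 14 lists passed with the deposited values, 13 with slide as a random block and 11 on 10 compounds only. RA 24 h versus RA 36 h had 5 on 10 compounds only, and RA 24 h versus Mock 36 h had 6 with the deposited values. With slide as a fixed block Docetaxel had 6 lists (1 shared), CM 8 (5 shared) and the mean of the compounds 5 (2 shared), and the cause was not tested.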

Other observations

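Between the RA schedules, some genes outside the lists that passed moved as well. Etv4, a target of FGF signals, and Lhx1, a gene of the primitive streak, were higher with RA for 24 h than for 36 h, by 1.10 and 1.45 on the log2 scale. Trh, an endoderm gene, was higher by 1.85, and Gdf3, a Nodal-related factor, by 1.65. Between the Mock arrays Etv4 was higher too, at 7.48 against 6.54, while Lhx1 (7.21 against 7.36), Trh (9.08 against 9.42) and Gdf3 (6.02 against 6.24) were lower. Gdf3 averaged 8.38 on the compound arrays with RA for 24 h and stood at 6.02 on Mock and 5.67 on CM.

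In CM, Pou5f1 and Nanog did not pass, at -0.06 (SE 0.553) and 0.03 (SE 0.344), each with the same sign in 1 of 2 schedules. With RA for 24 h Pou5f1 stood at 6.01 on CM against 7.07 on Mock, so the value near zero does not show that it was unchanged. Meis2, an RA-responsive homeobox gene, fell by 2.24 (adjusted p = 0.00217), with the same sign in 1 of 2 schedules. Hspb1, a small heat shock protein, fell by 1.22, and Txnip rose by 1.18.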
